A study of Mus musculus with 6 samples.

How the data were processed

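RNA from livers of male mice lacking apolipoprotein E, on the C57BL/6J background, was compared between a Western diet and the same diet with 1% squalene after 11 weeks. Per the labels, 9 control and 10 squalene-fed mice were combined into 4 RNA pools per diet, and 200 ng of RNA was labelled with Cy3 or Cy5. Each pool held the RNA of 2 or 3 animals; which animals went into which pool is not given in the sources used here. Every array carried 1 squalene pool and 1 Western pool, so the 6 arrays formed 4 pool pairs. Pairs 1 and 4 had squalene in Cy5 and pairs 2 and 3 had it in Cy3. Pairs 1 and 2 were each hybridised on 2 arrays, 1 on each of the 2 slides, and pairs 3 and 4 were on slide 2 alone. The pool pair was the replicate (n = 4), and repeat arrays of a pair counted once.

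The deposited scanner output gave spot and local background intensity in both channels, extracted with Agilent Feature Extraction 10.7.3.1 per the file headers. The same deposited files held intensity values that the scanner software had background-subtracted and dye-normalised, and log10 ratios of red over green, per the file headers. Other columns held the scanner software's marks for control spots, spot outliers and signal above background, per the file headers. The authors' deposited value table held log10 ratios whose processing is not given in the sources used here. Set against the scanner values, it equalled log10 of squalene over Western for the unnormalised median signals, within 0.001 for 99.93% to 99.94% of spots on each array, so its scale, centring and direction were all settled. Its column medians were 0.254 and 0.27 for the arrays of pair 1, -0.217 and -0.257 for those of pair 2, -0.27 for pair 3 and 0.259 for pair 4. A further 2 cells in each column of pair 1 held values too large for a log ratio and were left out.

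Each array had 62976 spots, of which 3671 were controls. Between 48.67% and 54.16% of spots were well above background in a channel, and none was saturated. Probes carried accessions without gene names, so symbols were taken from a RefSeq table of assembly GRCm38.p6, which named 26762 of 55681 probes; the files name an older build, so no coordinates are given. Near-identical family members such as the Cyp2b, Cyp2c and Cyp3a genes can share probe signal, and probe sequences were not used here.

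Values were computed in R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8. The planned background correction named mean spot signals; the files held median signals, which were used in their place. Signals were corrected with normexp (offset 50) and normalised within arrays by loess, with controls at weight 0 and spot outliers left out. Spots of a probe and repeat arrays of a pair were averaged. A probe was kept where it was well above background in at least 3 of the 4 pairs in the channel of at least 1 diet, which left 26853 probes and removed 28828. The brightest probe stood for each gene, giving 20659 features, 13312 with a symbol. limma's linear model (lmFit, eBayes) held a dye intercept and the squalene effect, with Benjamini-Hochberg adjustment over all features. The prior had 3.041 and the residual 2 degrees of freedom. The median SE of a log2 ratio was 0.07, against a median SD between pool pairs of 0.16. The SE is that of a mean over the 4 pairs, and the dye intercept takes up any difference between the 2 orientations, including one between the pools that happen to share an orientation. Diet levels were log2 intensities per channel after loess and Aquantile.

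A total of 574 entries in 30 gene lists, the named-gene rule, the tests and the alternative settings of the background correction, normalisation, probe filter, dye term, repeat arrays, slide, probes per gene, variance model and replicates were fixed before the data were examined. List shifts were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes. Named genes were to be the 12 with the largest rise and the 12 with the largest fall past an adjusted p of 0.05 with 1 sign in all 4 pairs. Where fewer passed, the smallest unadjusted p with 1 sign in all pairs filled the places, and up to 4 members of each list by smallest unadjusted p were added. For 3 genes that the rule takes, the single-gene results are not reported here; the list tests keep all measured members. Ces2a, Cyp3a11, Ces2c and Ugt2b34 fell outside that rule and were chosen after their values were seen, as were the genes named for single alternatives or single pool pairs. Restricting the test to features with a symbol, and recounting list members under each setting, were added after the data were seen.

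The fit was tested on simulated data for this comparison with 20659 genes. It called 46 of 50 genes changed 2-fold, 48 of 50 changed 4-fold, and 50 of 50 changed 8-fold and 16-fold. It also called 9 of 20459 unchanged genes, and camera called a moved list of 30 genes and 0 of 20 random lists. Noise was drawn from the fitted prior; an earlier version, which drew it from each gene's moderated variance, gave more false calls and was replaced. Simulated noise was independent between genes, unlike the real profiles, which differ between pools. The 200 simulated changes of 2-fold or more also ease the Benjamini-Hochberg threshold. The shares called are therefore not the chance of finding such changes in the real data. There Cyp2b10, 10.2-fold higher, had an adjusted p of 0.225 (limma, Benjamini-Hochberg). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.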

Results

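Squalene is an intermediate of cholesterol synthesis and enters the diet with olive oil and fish oils. Hepatic transcript levels were measured on two-colour mouse arrays in male mice lacking apolipoprotein E, which develop high plasma cholesterol and atherosclerosis. The mice received a Western diet with 0.15% cholesterol and 20% palm oil, alone (9 mice) or with 1% squalene (10 mice, equivalent to 1 g/kg), for 11 weeks. Per diet, 4 RNA pools were made, and each array set 1 squalene pool against 1 Western pool. The 6 arrays gave 4 pool pairs, squalene being in Cy5 in 2 of them and in Cy3 in the other 2. Repeat arrays of pairs 1 and 2 correlated across features at r = 0.828 and r = 0.866, with technical SDs of 0.09 on the log2 scale in both.

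The design asked which liver transcripts differ when squalene is added to the Western diet. Among features with a symbol, several of the highest ratios belonged to cytochrome P450 enzymes that metabolise drugs, led by Cyp2b10, the classic target of the nuclear receptor CAR. Cyp2b10 was 10.2-fold higher with squalene, with a log2 ratio of 3.35 ± 0.65 (SD, n = 4; SE 0.24). Its ratios were 2.98, 2.66, 3.65 and 4.10 in pairs 1 to 4, and its mean log2 intensity was 12.83 ± 0.66 in squalene pools and 9.49 ± 0.46 in Western pools. Cyp2c38, at 1.52 (SE 0.08), Cyp2c55, at 1.50 (SE 0.14), Cyp2b9, at 1.46 (SE 0.19), and Cyp2c29, at 1.08 (SE 0.07), were each above 0 in all 4 pairs. Their order is not firm: across other settings Cyp2c38 ran from 0.68, as the mean over its probes, to 1.54, Cyp2c55 from 1.40 to 2.14 and Cyp2b9 from 1.06 to 2.64. No feature of 20659 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment (0 genes). The smallest adjusted p was 0.158, for Cyp2c38 and Cyp2c29, and that of Cyp2b10 was 0.225, by the same limma test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 510 features, 217 higher and 293 lower, where chance alone gives 1032.95. That count ran from 364 to 1311 when 1 pool pair was left out and from 183 to 1124 across other settings. Other settings of the fit called between 0 and 13 features, and Cyp2b10 and Cyp2c55 were among those in each of the 5 settings with any.

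Of 36 listed target genes of CAR and PXR, nuclear receptors that switch on drug-metabolising enzymes, 30 were measured, 25 with a mean above 0. Ratios were above 0 in all 4 pairs for 13 of them, where chance gives 6.25%. By limma with Benjamini-Hochberg adjustment, 14 members passed 0.05 adjusted over the list alone, all higher, and 0 did over all genes. These were Cyp2b10, Cyp2b9, Cyp2c29, Cyp2c37, Cyp2c38, Cyp2c39, Cyp2c50, Cyp2c54, Cyp2c55, Cyp3a11, Cyp3a16, Ces2a, Ces2c and Ugt2b34. Cyp3a11, the main hepatic Cyp3a enzyme and a PXR target, was at 0.80 ± 0.37 (SD, n = 4). The carboxylesterases Ces2a and Ces2c, which hydrolyse ester drugs, were at 0.46 ± 0.16 and 0.31 ± 0.49, and the glucuronosyltransferase Ugt2b34 was at 0.23 ± 0.18 (SD, n = 4). The list averaged 0.51 (median 0.22), with 0.34, 0.48, 0.68 and 0.56 in the 4 pairs, and limma's camera gave it a Benjamini-Hochberg adjusted p of 5.43e-26. That call was lost with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.472) and by fry (Benjamini-Hochberg adjusted p = 0.376). A second, dimmer probe of Cyp2c38 read -0.16, and probes of these families may read each other's transcripts.

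**Figure D1:**
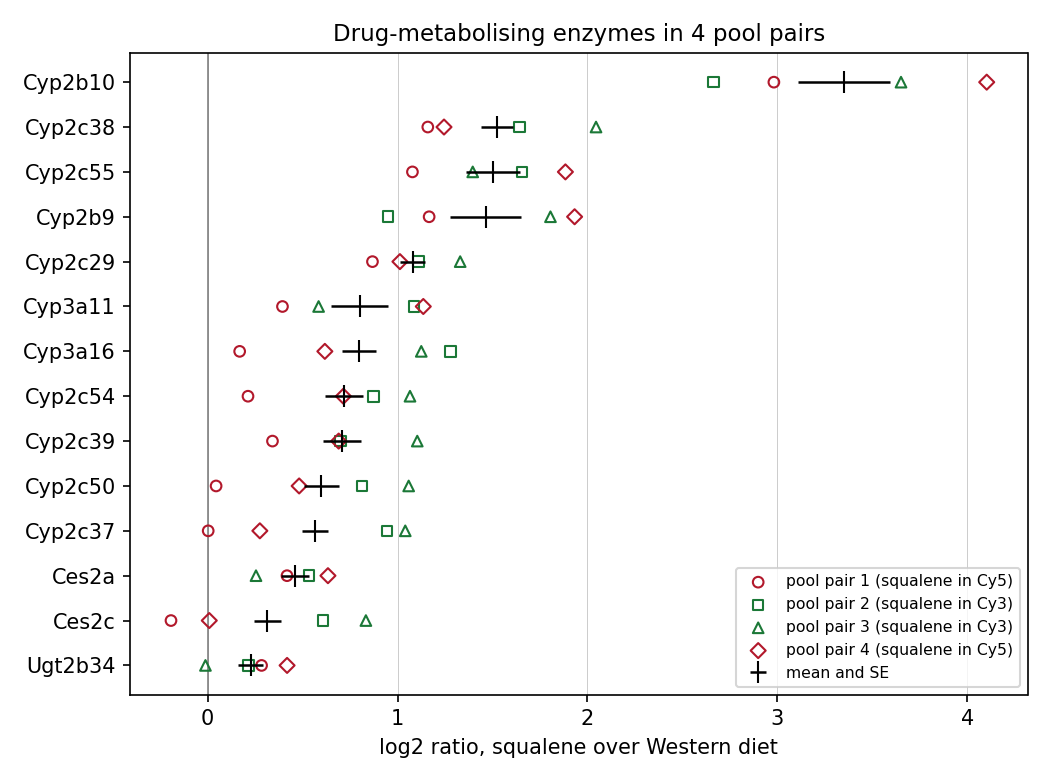
Log2 ratio of squalene over Western diet (x axis) for the 14 CAR and PXR target genes past 0.05 adjusted over the list alone (y axis), with 1 open symbol per pool pair, coloured by the dye of the squalene pool, and the mean with its SE in black. Cyp2b10 lies between 2.66 and 4.10 in the 4 pairs, while Ces2c in pair 1 (-0.19) and Ugt2b34 in pair 3 (-0.01) lie below 0.

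Among the other genes with the smallest unadjusted p and 1 sign in all pairs, the higher ones were Cyp3a16 at 0.80 (SE 0.09), Cyp3a41b at 0.74 (SE 0.12), Cyp2c54 at 0.72 (SE 0.10), Cyp2c39 at 0.71 (SE 0.10), Cyp2c50 at 0.60 (SE 0.09) and Cyp2c37 at 0.57 (SE 0.07). Serpinb1a, an inhibitor of neutrophil proteases, was at 0.42 (SE 0.06). The lower ones were led, by smallest unadjusted p and not by ratio, by the carboxypeptidase-like Cpxm1 at -0.63 (SE 0.07) and the chemokine Cxcl14 at -0.59 (SE 0.07). Ddit4, a stress-induced inhibitor of mTORC1, was at -0.67 (SE 0.13), Slc13a5, the hepatic citrate importer, at -0.41 (SE 0.07), and H2-Q1, a class I histocompatibility gene, at -0.40 (SE 0.07). Enc1 at -0.33, the creatine transporter Slc6a8 at -0.32, Arhgap22 at -0.32, Clstn3 at -0.31, Sema5b at -0.29, the collagen Col14a1 at -0.26 and the kinase Matk at -0.26 completed the group. All of these had adjusted p above 0.05 in limma with Benjamini-Hochberg adjustment. Their SEs leave out the difference between orientations that the dye intercept takes up. Between pairs the SD was 0.51 for Cyp2c37 (0.0029 in pair 1) and 0.44 for Cyp2c50 (0.04 in pair 1). It was 0.36 for Serpinb1a (0.03 in pair 3) and 0.40 for Cpxm1, against 0.04 for Col14a1.

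Genes of cholesterol synthesis, the pathway that squalene belongs to, had a list mean of 0.03 over 25 measured genes. Fdft1, the squalene synthase, was at 0.12 ± 0.07, Hmgcs1 at -0.40 ± 0.52 and Srebf2, the transcription factor of the pathway, at -0.22 ± 0.20 (SD, n = 4). Hmgcs1 ran from -0.70 to -0.098 when 1 pair was left out, and a second Srebf2 probe read 0.05. Lipoprotein genes averaged 0.00088 over 27 genes. Apoa4, an apolipoprotein of triglyceride-rich particles, was at 0.46 ± 0.18 and above 0 in all pairs, while the HDL receptor Scarb1, at -0.20 ± 0.05, the phospholipid transfer protein Pltp, at -0.22 ± 0.12, and Mylip, at -0.16 ± 0.05, were below 0 in all pairs (SD, n = 4). A second Mylip probe had the opposite sign. Fatty acid and triglyceride synthesis averaged 0.0026 over 24 genes, with Elovl6 at 0.34 ± 0.72, Fads2 at 0.18 ± 0.14, Agpat2 at -0.14 ± 0.19 and Scd1 at -0.27 ± 0.40 (SD, n = 4). In limma's camera the Benjamini-Hochberg adjusted p was 0.471 for cholesterol synthesis, 0.704 for lipoproteins and 0.719 for lipid synthesis. For lipoproteins, mean and median were above 0 and the test's direction below; for lipid synthesis the mean was above 0, the median (-0.02) and the test below.

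Lipid droplet genes averaged -0.09 (median -0.04) over 19 genes, with the list mean below 0 in all 4 pairs. Of the genes, 12 were below and 7 above 0 on average, and 2 were below 0 in every pair. Cidec, which enlarges lipid droplets, was at -0.56 ± 0.63, and the droplet coat proteins Plin4 and Plin5 were at -0.54 ± 0.47 and -0.20 ± 0.13, with Cidea at -0.09 ± 0.07 (SD, n = 4). When 1 pair was left out Plin4 ran from -0.73 to -0.36 and Plin5 from -0.28 to -0.13. No member passed 0.05 adjusted over the list alone or over all genes (limma, Benjamini-Hochberg; 0 and 0, with 3 at an unadjusted p under 0.05). The list's adjusted p was 0.0226 by camera with Benjamini-Hochberg adjustment, and 0.56 with an estimated correlation. That call was also lost without replicate 2, 3 or 4 (camera, Benjamini-Hochberg adjusted p = 0.243, 0.0580 and 0.0652). Fatty acid oxidation genes averaged -0.06 over 33 genes (camera, Benjamini-Hochberg adjusted p = 0.392), with Pdk4 at -0.57 ± 0.95, Decr2 at 0.23 ± 0.27, Acaa1b at -0.16 ± 0.18 and Acaa2 at -0.08 ± 0.06 (SD, n = 4). Bile acid synthesis and transport averaged 0.06 over 22 genes (camera, Benjamini-Hochberg adjusted p = 0.322). The efflux pumps Abcc3 and Abcc2 were at 0.24 ± 0.10 and 0.16 ± 0.12, and the uptake carrier Slco1a4 was at 0.78 ± 0.62, all above 0 in every pair, while the nuclear receptor Nr0b2 was at -0.24 ± 0.25 (SD, n = 4). Slco1a4 ran from 0.43 to 1.14 when 1 pair was left out.

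Markers of lipid-associated macrophages, cells that take up lipid in fatty liver and plaque, averaged -0.35 over 10 genes. Gpnmb was at -0.85 ± 0.93 (SE 0.13), the lipid receptor Trem2 at -0.55 ± 0.61 (SE 0.10), Itgax at -0.33 ± 0.46 (SE 0.08) and the lipase Lpl at -0.39 ± 0.67 (SE 0.14; SD, n = 4). Gpnmb, Trem2 and Itgax passed 0.05 adjusted over the list alone and 0 members did over all genes (limma, Benjamini-Hochberg). Stellate cell and fibroblast markers averaged -0.16 over 15 genes, and 4 passed 0.05 adjusted over the list alone and 0 over all genes (limma, Benjamini-Hochberg). These were Lum at -0.35 ± 0.51, Col1a2 at -0.38 ± 0.64, Col1a1 at -0.47 ± 0.86 and Timp1, an inhibitor of matrix proteases, at -0.45 ± 1.00 (SD, n = 4). Of the 15, 3 were above 0, among them the myofibroblast markers Acta2 at 0.36 ± 0.43 (0.60 in pair 2) and Tagln at 0.15 ± 0.14 (SD, n = 4). By camera the Benjamini-Hochberg adjusted p was 1.48e-11 for the macrophage and 3.94e-07 for the fibroblast list, and both were lost with an estimated correlation (adjusted p = 0.472) and by fry (adjusted p = 0.376). The low values came from pairs 2 and 3, with squalene in Cy3, where the macrophage list averaged -0.63 and -0.77 against 0.14 and -0.16 in pairs 1 and 4, and the fibroblast list -0.41 and -0.43 against 0.19 and 0.01. Without the dye term 0 members of either list passed (limma, Benjamini-Hochberg over the list alone), and the fibroblast count was also 0 with median centring, with the deposited table and without replicate 4. Elsewhere the macrophage count ran from 2 to 7 and the fibroblast count from 3 to 7.

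**Figure D2:**
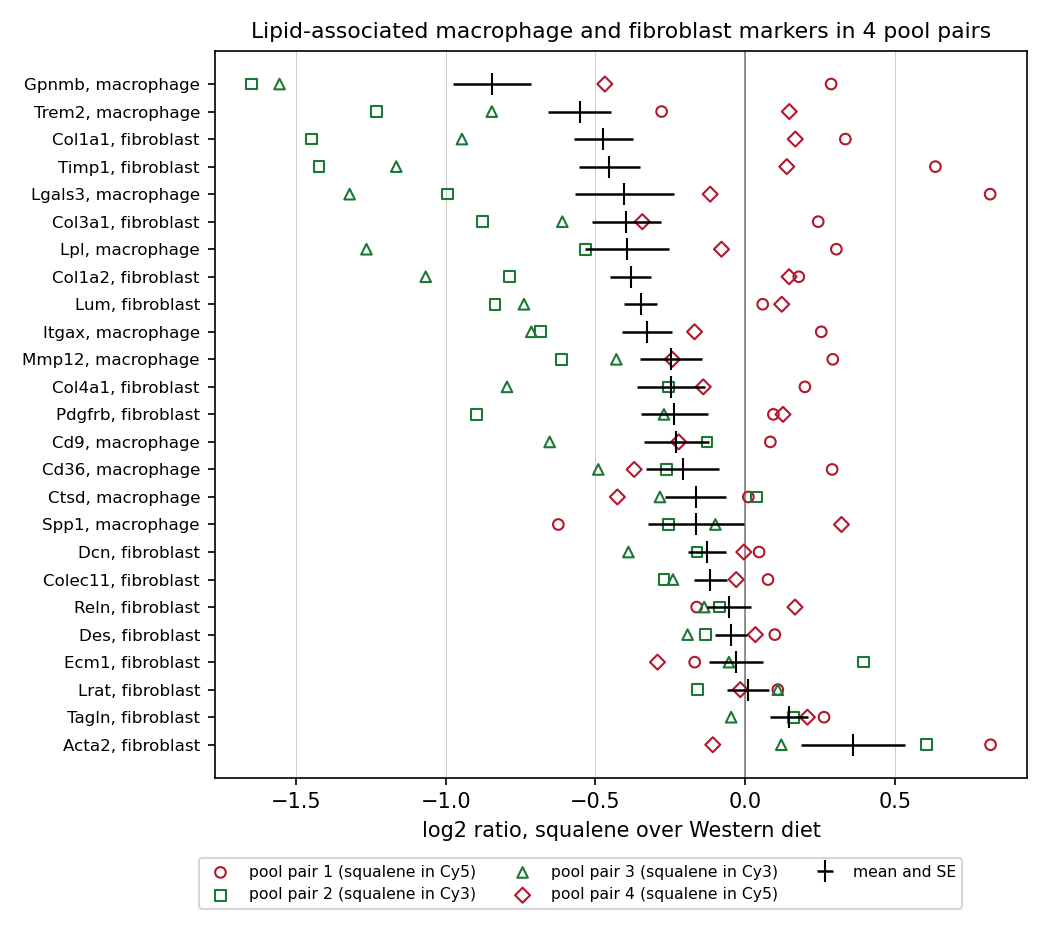
Log2 ratio of squalene over Western diet (x axis) for each measured lipid-associated macrophage and fibroblast marker (y axis), with 1 open symbol per pool pair, coloured by the dye of the squalene pool, and the mean with its SE in black. Gpnmb lies at -1.65 and -1.55 in pairs 2 and 3 and at 0.29 and -0.47 in pairs 1 and 4.

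Red cell transcripts averaged -0.36 over 8 genes, with Hba-a1 at -0.54 ± 0.81, Hba-a2 at -0.50 ± 1.17, Hbb-bt at -0.54 ± 0.80 and Hbb-b2 at -0.48 ± 0.78 (SD, n = 4). Their low values came from pairs 2 and 3, as for the macrophage and fibroblast markers, at -0.45 and -1.20 against 0.07 and 0.14 in pairs 1 and 4, and the mean ran from -0.55 to -0.17 when 1 pair was left out. Kupffer cell and macrophage markers averaged -0.18 over 17 genes, with the endotoxin co-receptor Cd14 at -0.32 ± 0.35, Ctss at -0.28 ± 0.56, Tyrobp at -0.26 ± 0.36 and the complement gene C1qa at -0.19 ± 0.23 (SD, n = 4). Neutrophil markers averaged -0.19 over 5 genes, with S100a9 at -0.44 ± 0.67, S100a8 at -0.40 ± 0.66, Camp at -0.10 ± 0.10 and Elane at -0.05 ± 0.07 (SD, n = 4). Acute phase genes averaged -0.09 over 29 genes, and the serum amyloids Saa1, Saa2 and Saa3 were at -0.34 ± 0.58, -0.39 ± 0.79 and -0.36 ± 0.44, with Lcn2 at -0.36 ± 0.64 (SD, n = 4). No member of these 4 lists passed 0.05 adjusted over the list alone or over all genes in limma with Benjamini-Hochberg adjustment (0 each; at an unadjusted p under 0.05, 4 red cell, 1 Kupffer, 0 neutrophil and 1 acute phase member). The camera adjusted p (Benjamini-Hochberg) was 3.94e-07 for red cell, 2.76e-05 for Kupffer, 0.0236 for neutrophil and 0.0013 for acute phase genes. With an estimated correlation the adjusted p was 0.56, 0.839, 0.56 and 0.839 in the same order. When 1 pair was left out the Kupffer mean ran from -0.37 to 0.017, the neutrophil mean from -0.29 to -0.097 and the acute phase mean from -0.17 to -0.011; camera's call ended without replicate 3 for the neutrophil list and without replicate 3 or 4 for the Kupffer and acute phase lists.

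Endoplasmic reticulum chaperones and stress genes averaged 0.11 over 28 genes, 24 of them with a mean above 0 but 0 above 0 in all 4 pairs. The list averaged -0.016, 0.38, 0.0062 and 0.071 in pairs 1 to 4, so most of its mean came from pair 2. Creld2 was at 0.52 ± 0.78, Trib3 at 0.25 ± 0.50, Dnajb9 at 0.25 ± 0.52 and Manf at 0.16 ± 0.31 (SD, n = 4). Female-biased liver genes averaged 0.23 (median 0.13) over 9 genes, 7 above and 2 below 0. Cyp3a16 and Cyp2b9, which also stand in the CAR and PXR list, passed 0.05 adjusted over the list alone and 0 members passed over all genes (limma, Benjamini-Hochberg). The list mean above 0 rests on Cyp2b9 (1.46) and Cyp3a16 (0.80), so it is not separate from the CAR and PXR result. Fmo2, a flavin monooxygenase, was at 0.10 ± 0.17 (SD, n = 4). By camera the Benjamini-Hochberg adjusted p was 2.86e-06 for the chaperones and 0.0032 for the female-biased genes. With an estimated correlation the adjusted p was 0.671 and 0.56. When 1 pair was left out the means ran from 0.017 to 0.21 and from 0.070 to 0.39, with camera's call lost at the lowest value of each, and Creld2 ran from 0.25 to 0.79.

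The hepatocyte markers averaged 0.04 over 14 genes (camera, Benjamini-Hochberg adjusted p = 0.225), with Cps1 at 0.16 ± 0.44, Hpd at 0.16 ± 0.27 and Apoa1 at 0.08 ± 0.16 (SD, n = 4). Camera adjusted p (Benjamini-Hochberg) also stayed above 0.05 for immediate early genes (mean 0.10, adjusted p = 0.413), clock genes (0.10, adjusted p = 0.112), glucose metabolism (0.05, adjusted p = 0.619), aryl hydrocarbon receptor targets (0.05, adjusted p = 0.682), antioxidant genes (0.03, adjusted p = 0.451), proliferation markers (0.02, adjusted p = 0.879), respiratory chain subunits (0.02, adjusted p = 0.392) and lymphocyte markers (0.01, adjusted p = 0.451). Below 0 on average, with camera adjusted p (Benjamini-Hochberg) above 0.05, were male-biased genes (-0.03, adjusted p = 0.937), exocrine pancreas (-0.03, adjusted p = 0.698), endothelial markers (-0.04, adjusted p = 0.143), interferon-stimulated genes (-0.06, adjusted p = 0.112), bile duct markers (-0.07, adjusted p = 0.225) and adipocyte markers (-0.18, adjusted p = 0.682). Mean and median differed in sign for the receptor targets, the pancreas list and the adipocyte list. In none of these 15 lists did a member pass 0.05 adjusted over the list alone or over all genes (limma, Benjamini-Hochberg).

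The members of these lists with the smallest unadjusted p all had adjusted p above 0.05 in limma with Benjamini-Hochberg adjustment. Of the immediate early genes, which respond to acute signals, Nr4a1 was at 0.49 ± 1.52, Jun at 0.18 ± 1.11, Ier2 at 0.17 ± 0.76 and Fosb at 0.16 ± 0.77 (SD, n = 4). Of the clock genes, Per1 was at 0.28 ± 0.55, Per2 at 0.30 ± 0.69, Tef at 0.25 ± 0.67 and Nr1d1 at 0.10 ± 0.14 (SD, n = 4). Of the glucose genes, Pfkfb3 was at 0.44 ± 0.57, Pcx at -0.20 ± 0.33, Igfbp2 at 0.12 ± 0.16 and Fbp1 at -0.11 ± 0.11 (SD, n = 4). Of the dioxin-responsive receptor targets, Cyp1a2 was at 0.39 ± 0.55, Ugt1a6a at 0.14 ± 0.20, Tiparp at -0.088 ± 0.20 and Cyp1b1 at -0.042 ± 0.43 (SD, n = 4). Of the antioxidant genes, the glutathione transferases and the NRF2 repressor read Gstm4 at 0.30 ± 0.36, Gstm3 at 0.29 ± 0.39, Gstm2 at -0.10 ± 0.22 and Keap1 at 0.16 ± 0.18 (SD, n = 4). Proliferation markers included Birc5 at 0.21 ± 0.67, Rrm2 at 0.16 ± 0.44, Mcm4 at -0.073 ± 0.35 and Mcm7 at -0.078 ± 0.22 (SD, n = 4). Lymphocyte markers included Gzma at 0.29 ± 0.44, Gzmb at 0.14 ± 0.25, Ms4a1 at 0.21 ± 0.50 and H2-Aa at -0.27 ± 0.73 (SD, n = 4). Respiratory chain subunits included Ndufs1 at 0.10 ± 0.28, Uqcrfs1 at 0.063 ± 0.063, Ndufs3 at 0.06 ± 0.13 and Atp5c1 at 0.057 ± 0.11 (SD, n = 4). Male-biased genes included Elovl3 at -0.43 ± 1.29, Slco1a1 at 0.12 ± 0.48, Cyp2d9 at 0.062 ± 0.53 and Cyp7b1 at 0.12 ± 0.61 (SD, n = 4). Interferon-stimulated genes included Rsad2 at -0.22 ± 0.19, Oas1a at -0.21 ± 0.55, Ifit3 at -0.16 ± 0.30 and Cxcl9 at 0.26 ± 0.73 (SD, n = 4). Endothelial markers included Lyve1 at -0.11 ± 0.46, Gpr182 at -0.11 ± 0.26, Bmp2 at -0.061 ± 0.11 and Stab2 at -0.052 ± 0.22 (SD, n = 4). Bile duct markers included Sox9 at -0.15 ± 0.31, Krt7 at -0.067 ± 0.087, Cldn7 at 0.043 ± 0.20 and Spp1 at -0.16 ± 0.39 (SD, n = 4). Pancreas and adipocyte markers included Cela1 at -0.25 ± 0.23, Amy2a5 at 0.065 ± 0.25, Clps at 0.013 ± 0.025, Cela2a at 0.015 ± 0.20, Cfd at -0.80 ± 1.09, Adig at 0.059 ± 0.13, Lipe at 0.016 ± 0.24 and Fabp4 at -0.0041 ± 0.35 (SD, n = 4), and Cfd ran from -1.19 to -0.41 when 1 pair was left out.

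**Figure D3:**
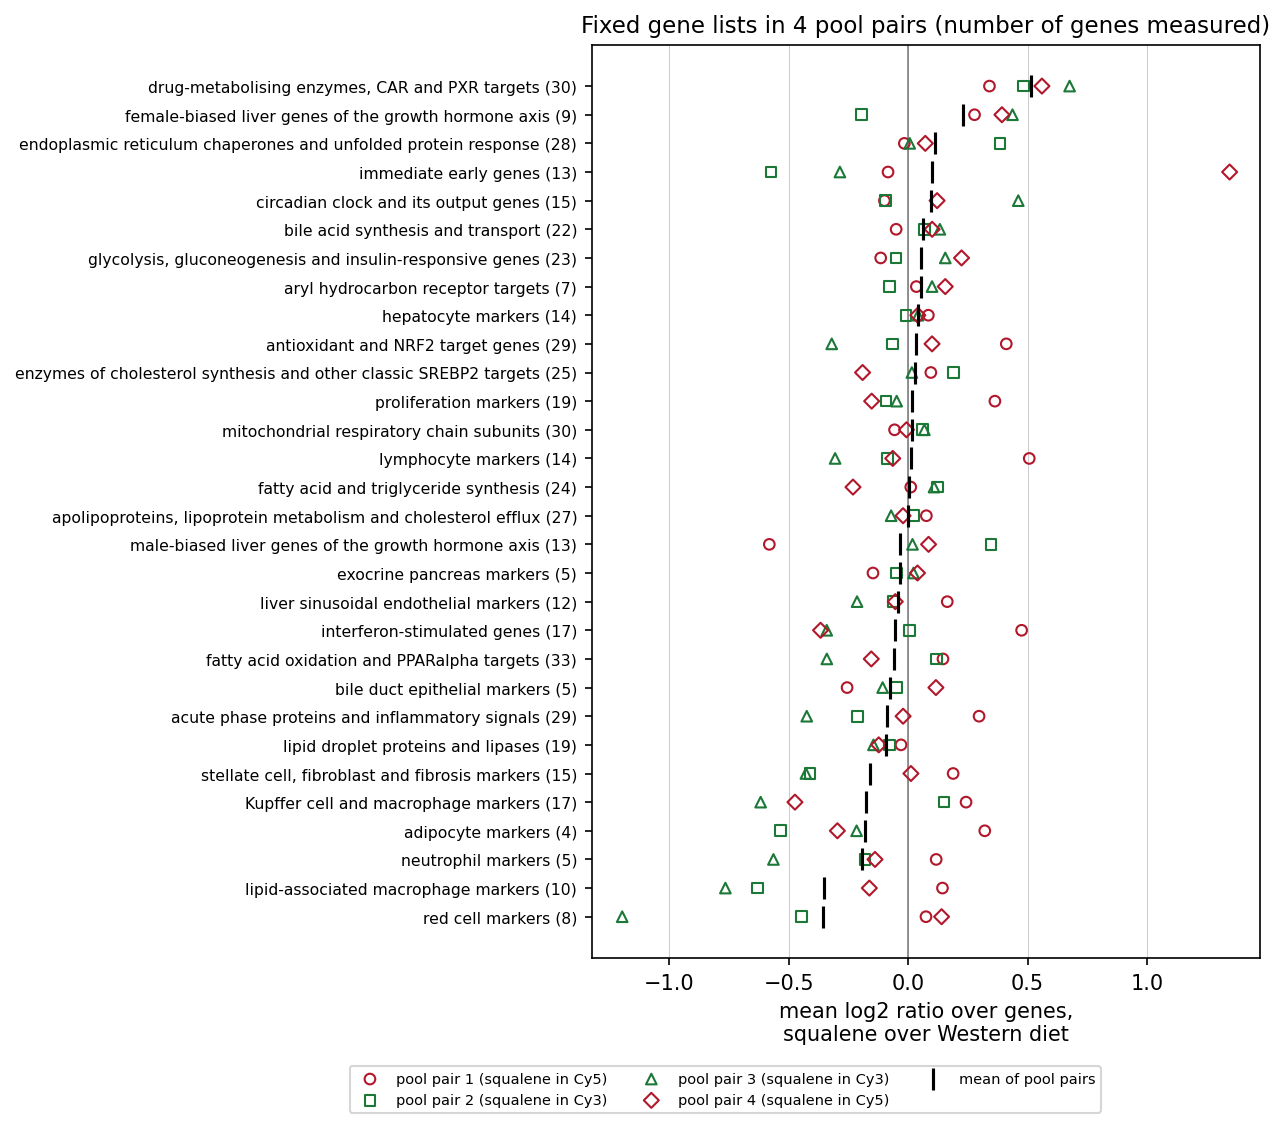
Mean log2 ratio of squalene over Western diet (x axis) of each of the 30 gene lists (y axis, with the number of genes measured), with 1 open symbol per pool pair, coloured by the dye of the squalene pool, and a black bar at the mean of the 4 pairs. The CAR and PXR targets lie between 0.34 and 0.68, and immediate early genes between -0.57 and 1.35.

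Pool pairs differed more from each other than repeat arrays did. Of the 139 genes compared across settings, 53 kept their sign but moved by more than 1.5 times when 1 pair was left out, and 28 turned sign. Across features, which are not independent replicates, the log2 ratios of squalene over Western correlated at r = -0.428 between pairs 1 and 3 and r = -0.409 between pairs 2 and 4, at -0.135 and 0.157 for pairs 1 and 2 and for pairs 2 and 3, and at 0.078 and -0.023 for pairs 1 and 4 and for pairs 3 and 4. Ratios had the same sign in all 4 pairs for 1319 features (6.38%), where independent signs give 12.5%. The direction of each ratio rests on the dyes in the labels; Cyp2b10, Cyp2b9, Cyp2c29, Cyp2c38 and Cyp2c55 were above 0 in every pair under those dyes.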

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

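All tests in this part were set before the data were examined, and the genes come from the named-gene rule, apart from the 4 chosen after their values were seen. Among 169 genes and lists, 7 had 1 pool pair far from the other 3, measured as its gap to the nearest pair over the whole range, where chance gives about 8.45.

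The gap was 0.993 for Scd1, the desaturase that makes oleate, at -0.87 in pair 4 and between -0.07 and -0.06 in the other pairs. It was 0.946 for the immediate early receptor Nr4a1, at 2.77 in pair 4, and 0.856 for the immediate early factor Fosb, at 1.30 in pair 4. It was 0.839 for Fabp4, a fatty acid binding protein of fat cells and macrophages, at 0.52 in pair 1, and 0.838 for the B cell marker Ms4a1, at 0.95 in pair 1. It was 0.838 for Fmo2, at -0.15 in pair 4, and 0.834 for the clock output factor Tef, at 1.23 in pair 3. No explanation of these single values was tested, and a count of 7 is no more than chance gives.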

How the results depend on the processing

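Restricting the test to features with a symbol and recounting list members under each setting were chosen after the data were seen; the other settings were planned. Of the tested comparisons with the reported value, 2986 for single genes and 638 for lists kept direction and side of the threshold, and 41 and 31 reversed. With the direction kept, 29 gene and 22 list comparisons newly passed a threshold and 29 list comparisons no longer did; of the reversed list comparisons a further 6 newly passed it and 2 no longer did. On slide 1 alone, without a test, 108 of 139 genes and 21 of 30 lists kept their sign, and Abcc3 (0.36), Elane (-0.14) and Cidea (-0.17) moved by more than 1 SD. The cause was not tested unless named. No setting moved the median of all features by more than 0.1. Between 48.67% and 54.16% of spots were well above background, and the 28828 probes removed as dim were not tested in the reported fit.

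The count of features past an adjusted p of 0.05 (limma, Benjamini-Hochberg) was 0 and became 2 with median centring, 8 with the deposited table, 12 with the 6 arrays fitted with the pair as a random block, 4 with a slide term added to that block and 13 with the separate-channel fit. It was 510 at an unadjusted p of 0.05 and 0 in the remaining settings. The 510 became 201 with median centring, 183 with the deposited table, 935 without a filter on dim probes, 254 without the dye term, 1124 with the separate-channel fit, 1311 without replicate 2 and 868 without replicate 3, on both sides of the 1032.95 that chance gives for the reported features. Besides Cyp2b10, Cyp2c55, Cyp2c38, Cyp2c29, Cyp2b9, Cyp3a16, Cyp2c54 and Cyp3a41b, these calls included Cyp3a59, Cpxm1, Emp1, Cxcl14 and 2 unnamed probes, chosen here after their values were seen. The block and separate-channel fits use more residual degrees of freedom because they count repeat arrays or channels, at correlations of 0.765, 0.867 and 0.821.

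The CAR and PXR mean of 0.51 lost its call with camera at an estimated correlation and by fry; with the preset correlation it stayed past camera's threshold in each tested processing setting, between 0.42 and 0.59, and between 0.46 and 0.57 without 1 replicate. The count of its members past 0.05 adjusted over the list alone (limma, Benjamini-Hochberg) was 14 and ran from 11 without the dye term to 18 with all probes tested. For lipid-associated macrophages it was 3 and ran from 0 without the dye term to 7 with the separate-channel fit. For fibroblasts it was 4, became 0 without the dye term, with median centring, with the deposited table and without replicate 4, and was 7 with the separate-channel fit. The means of the 10 lists called by camera are not altered by the choice of gene set test, but with an estimated correlation and by fry none passed: CAR and PXR targets 0.51, lipid-associated macrophages -0.35, red cells -0.36, fibroblasts -0.16, chaperones 0.11, Kupffer cells -0.18, acute phase -0.091, female-biased genes 0.23, lipid droplets -0.095 and neutrophils -0.19.

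With the deposited table, camera (Benjamini-Hochberg) also called bile acid genes at 0.081, adipocyte markers at -0.18, bile duct markers at -0.080, clock genes at 0.11, immediate early genes at 0.11 and interferon genes at -0.040. Without a filter on dim probes the female-biased mean fell short of the threshold at 0.11. On slide 1 alone, a value with no test, the acute phase mean was 0.042 and the Kupffer mean 0.20, opposite to the reported signs of these called lists. Lists that were not called turned there too: immediate early genes at -0.33, interferon genes at 0.23, fatty acid oxidation at 0.14, glucose metabolism at -0.10, clock genes at -0.085, aryl hydrocarbon receptor targets at -0.041 and endothelial markers at 0.051; only pairs 1 and 2 are on that slide. Means near 0 turned sign: lipid synthesis at -9e-04 with an offset of 16 and -0.013 with the scanner software's processed signals, lipoproteins at -0.0014 and -0.0045 with these and at -0.0024 with only the arrays of slide 1 for repeated pairs, and lymphocyte markers at -7e-04 with all probes. Among genes in the tested settings with all pool pairs, Fabp4 (-0.0041 as reported) was at 8e-04 without background subtraction, 0.02 with median centring, 0.019 with the deposited table, 0.007 with the block, 0.002 with the block and slide term and 0.013 with only the arrays of slide 1 for repeated pairs. Lipe was at -0.053 and -0.0097 with processed signals and with only those arrays, and Clps at -0.018 with processed signals. Further genes kept their sign but moved by more than 1.5 times. With processed signals Cyp2b9 was at 2.64, H2-Q1 at -0.63, Cela1 at -0.61, Arhgap22 at -0.50 and Sema5b at -0.45, and Cyp2c38 was at 0.68 as the mean over its probes, of which the dimmer read -0.16. On slide 1 alone, without a test, 31 genes turned sign; the 12 with the largest moves were Nr4a1 at -0.21, Jun at -0.37, Elovl3 at 0.097, Pfkfb3 at -0.076, S100a9 at 0.053, Fosb at -0.33, S100a8 at 0.064, Per2 at -0.16, Cyp7b1 at -0.30, Per1 at -0.094, Ctss at 0.074 and Oas1a at 0.14. Others kept their sign but moved by more than 1.5 times, such as Hmgcs1 at -0.0051, Cyp1a2 at 0.05, Saa3 at -0.069, Scd1 at -0.059, Lpl at -0.12, Slco1a4 at 0.31, Gstm3 at 0.64, Gstm4 at 0.60 and Cxcl9 at 0.72.

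Leaving out 1 pool pair at a time changed the sign or call of many list means, given here as lowest and highest. Chaperones ran from 0.017 to 0.21, acute phase from -0.17 to -0.011, bile acids from 0.025 to 0.10, adipocyte markers from -0.34 to -0.027, bile duct markers from -0.17 to 0.018, proliferation from -0.11 to 0.15 and endothelial markers from -0.096 to 0.012. Kupffer markers ran from -0.37 to 0.017, lymphocyte markers from -0.13 to 0.15, neutrophil markers from -0.29 to -0.097, pancreas from -0.081 to 0.013, cholesterol synthesis from -0.044 to 0.099, clock genes from -0.042 to 0.24 and fatty acid oxidation from -0.17 to 0.057. Female-biased genes ran from 0.070 to 0.39, glucose metabolism from -0.032 to 0.14, immediate early genes from -0.26 to 0.46, interferon genes from -0.27 to 0.15, lipid droplets from -0.12 to -0.071, lipid synthesis from -0.058 to 0.063, lipoproteins from -0.024 to 0.025, male-biased genes from -0.2 to 0.13 and antioxidant genes from -0.044 to 0.11. Red cells kept sign and call but ran from -0.55 to -0.17, the smallest without replicate 3, whose pair mean was -1.20. Camera's call (Benjamini-Hochberg) ended for chaperones without replicate 2, for lipid droplets without replicate 2, 3 or 4, for female-biased and neutrophil genes without replicate 3, and for Kupffer and acute phase genes without replicate 3 or 4. It appeared with the opposite sign for proliferation, lymphocyte, lipid synthesis and male-biased genes without replicate 1, and for immediate early and interferon genes without replicate 4. With the sign kept it appeared for bile acid, adipocyte, endothelial, glucose and immediate early genes without replicate 1, interferon genes without replicate 1 or 2, clock and fatty acid oxidation genes without replicate 2, antioxidant genes without replicate 3 or 4, and bile duct, proliferation, lymphocyte, cholesterol synthesis and male-biased genes without replicate 4.

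Named genes whose sign turned when 1 pool pair was left out, again as lowest and highest, were these. Tiparp ran from -0.20 to 0.023, Cyp1b1 from -0.087 to 0.0027, Lipe from -0.056 to 0.087, Fabp4 from -0.16 to 0.16, Sox9 from -0.34 to 0.03, Spp1 from -0.40 to 0.072, Cldn7 from -0.070 to 0.16 and Rrm2 from -0.096 to 0.41. Mcm4 ran from -0.18 to 0.036, Birc5 from -0.20 to 0.61, Mcm7 from -0.18 to 0.027, Gpr182 from -0.24 to 0.029, Stab2 from -0.11 to 0.0035, Ms4a1 from -0.028 to 0.44 and Cela2a from -0.072 to 0.10. Tef ran from -0.047 to 0.54, Per2 from -0.066 to 0.67, Nr4a1 from -0.25 to 1.22, Ier2 from -0.088 to 0.44, Jun from -0.21 to 0.58, Fosb from -0.25 to 0.56, Ifit3 from -0.34 to 0.011 and Oas1a from -0.45 to 0.036. Cxcl9 ran from -0.14 to 0.66, Slco1a1 from -0.020 to 0.26, Elovl3 from -1.18 to 0.32, Cyp2d9 from -0.072 to 0.20 and Cyp7b1 from -0.11 to 0.36. Of the 139 genes, these were 28; another 53 kept their sign but moved by more than 1.5 times. The widest ranges were those of Cfd (-1.19 to -0.41), Slco1a4 (0.43 to 1.14), Hmgcs1 (-0.70 to -0.098), Per1 (0.0059 to 0.55), Creld2 (0.25 to 0.79), Hbb-bt (-0.79 to -0.29), Hbb-b2 (-0.73 to -0.23), S100a9 (-0.69 to -0.19) and Pfkfb3 (0.19 to 0.69). Next came Cyp1a2 (0.14 to 0.64), H2-Aa (-0.52 to -0.031), Pdk4 (-0.80 to -0.34), Hba-a2 (-0.73 to -0.27), Saa2 (-0.61 to -0.16), S100a8 (-0.63 to -0.18), Hba-a1 (-0.75 to -0.32), Saa1 (-0.56 to -0.13) and Scd1 (-0.47 to -0.063). Narrower ranges were those of Gstm3 (0.098 to 0.49), Tyrobp (-0.44 to -0.076), Plin4 (-0.73 to -0.36), Lpl (-0.58 to -0.21), Ctss (-0.46 to -0.10), Gstm4 (0.13 to 0.48), Saa3 (-0.52 to -0.20), Hpd (0.0077 to 0.32) and Lcn2 (-0.50 to -0.21). After these stood Gzmb (0.016 to 0.27), Dnajb9 (0.14 to 0.36), Acaa1b (-0.27 to -0.062), Cps1 (0.061 to 0.26), Decr2 (0.13 to 0.33), Pcx (-0.30 to -0.099), C1qa (-0.29 to -0.092), Keap1 (0.075 to 0.25) and Fmo2 (0.015 to 0.19). Then came Nr1d1 (0.024 to 0.18), Plin5 (-0.28 to -0.13), Lyve1 (-0.18 to -0.032), Ugt1a6a (0.064 to 0.21), Pltp (-0.29 to -0.14), Abcc2 (0.093 to 0.23), Apoa1 (0.016 to 0.14), Adig (0.003 to 0.12) and Gstm2 (-0.14 to -0.061). The narrowest were those of Bmp2 (-0.10 to -0.021), Amy2a5 (0.025 to 0.10), Camp (-0.14 to -0.062), Krt7 (-0.10 to -0.034), Acaa2 (-0.11 to -0.045), Ndufs3 (0.034 to 0.087), Elane (-0.076 to -0.026) and Clps (0.003 to 0.022).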

Other observations

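The tests in this part were chosen after the result was seen, except the counts of other sign patterns and the second-probe correlation. Mean ratios of some gene lists varied between single pool pairs, shown here for pairs picked by size and without a test. The 7 items flagged above for a far pool pair were all genes, not lists. Immediate early genes, which respond within minutes to stress and handling, averaged 1.35 in pair 4 and -0.57 in pair 2, with Jun at 1.72 and Ier2 at 1.23 in pair 4. Interferon-stimulated genes averaged 0.47 in pair 1 and -0.37 in pair 4, with the chemokine Cxcl9 at 1.33 in pair 1. Clock genes averaged 0.46 in pair 3, where Per2 was at 1.31 and Per1 at 1.05. Male-biased genes averaged -0.58 in pair 1, and the fatty acid elongase Elovl3 was at -2.12 in pair 3 and 0.88 in pair 2.

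The mean of the CAR and PXR target genes was above 0 in all 4 pool pairs (0.51, median 0.22 over genes), as were all 4 ratios of 13 of the 30 members. Dye bias alone would put the mean below 0 in 1 dye orientation. It was 0.45 (SE 0.14 over members) in the lower and 0.58 in the higher orientation. These values follow from a mean above 0 in all 4 pairs and are no separate test, though dye bias alone would not give that pattern. A larger share of hepatocyte RNA would raise hepatocyte markers alike, but the list lay 0.48 (SE 0.13 over genes) above them. Genes of a list are not independent replicates, so that SE measures no spread between pools, and this list had the highest mean of the 30. In pairs 1 to 4 the list averaged 0.34, 0.48, 0.68 and 0.56, against 0.08, -0.009, 0.04 and 0.04 for the markers. A single induced gene read by its relatives would stay within 1 family, but 3 families held members higher in all pairs. Within a family that stays open, since the second Cyp2c38 probe read -0.16 and no probe sequence was used, and 1 of the 7 sign patterns of the pairs, the real one, shifted the list as much (0.51, highest other 0.42), which are too few patterns for a share under 0.05. A response to squalene stays open, and no mechanism was tested.

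The profiles of some pool pairs opposed each other (r = -0.428 and -0.409). A wrong dye record would turn targets with a shared response negative in a pair, but 5 of 5 were positive in all pairs. These 5 were picked for a mean above 2-fold over the same pairs under the recorded dyes. The choice partly fixes the count, which does not decide. A shared dye bias as the whole cause would leave alike the 2 contrasts of squalene over Western ratios that are free of dye and diet. That of pairs 1 and 2 against 3 and 4 had 2.26 times the variance of the other over features (95% bootstrap interval over features 2.14 to 2.39). Features are not independent replicates, so the interval measures no spread between pools. The excess describes these 4 pairs alone. Since only pairs 1 and 2 had arrays on slide 1, a difference between slides would end that excess on slide 2 alone, where the ratio was 2.21 (2.10 to 2.34), while a shared dye bias as a part of the cause stays open: the mean red over green ratio had 1.31 times the variance of that contrast (SD over features 0.15 against 0.131, with 0.087 for the other contrast and 0.095 for squalene), and all 6 correlations of red over green between pairs were above 0 (0.023 to 0.428), but pools that share an orientation also enter that mean. On the contrast of pairs 1 and 2 against 3 and 4, 19 of 30 lists lay outside the middle 95% of random lists. On the other contrast 14 did. Random lists were drawn gene by gene, without the co-expression within real lists. Lists of co-expressed genes can therefore fall outside on many contrasts, and the counts do not decide. A difference of pools in whole gene programs stays open, and what set pools apart between animals is not tested here. The counts of the diet test were not particular to the real sign pattern. Of 7 patterns, the real one included, 5 gave at least as many features at an unadjusted p under 0.05 (510 for the real one, highest other 2590). For lists called by camera it was 4 of 7, again with the real one included (10, highest other 18). With 7 patterns no share under 0.05 is possible. The pattern with 2590 features (2528 on slide 2 alone) sets pairs 1 and 2 against pairs 3 and 4 in their squalene over Western ratios. What set these pairs apart was not tested.

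Lipid-associated macrophage and collagen markers were lower with squalene mainly in pairs 2 and 3, both with squalene in Cy3. Dye bias of their probes as the whole cause would cancel over both orientations. The mean there was -0.24 (SE 0.05 over markers, 0.06 over pool pairs within orientations). These lists were picked for a mean below 0, so that mean restates the pattern and does not decide. Markers are also not independent replicates, and the SE over pool pairs rests on 2 degrees of freedom. The planned test of bias in single probes, a correlation of 0.801 between brightest and second probes, covered 3 of 25 markers and decides nothing. The markers' mean red over green ratio (0.29, at percentile 100 of random lists) only restates the pattern they were picked for. Dye bias as the whole or a part of the split between orientations stays open. A lower share of macrophages in the squalene pool would lower Kupffer markers alike. In pair 2 these had a mean of 0.15 and lay 0.78 (SE 0.20 over markers) above the lipid-associated markers. That gap rests on 1 pool pair singled out for low lipid-associated markers, and markers of a list are not independent replicates. The Kupffer mean shows only that these markers were not lower there as a set. In pair 3 the gap was 0.15 (SE 0.16 over markers) with Kupffer markers at -0.62. A lower macrophage share stays open there for the macrophage markers alone. It would not cover the fibroblast markers, at -0.43 in pair 3, which are not macrophage transcripts. Whether squalene or the animals in each pool set the macrophage and collagen markers is untested, since orientation, pool and diet are crossed in only 4 pairs.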
